A study of Homo sapiens with 3 samples.

How the data were processed

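RNA was measured in 3 A375SM melanoma populations carrying lentiviral hairpin vectors with a green fluorescent reporter: shPRAME, shBAP1 and shEmpty, with 1 library each. Per the labels, cells positive for the reporter were selected into stable populations, total RNA was extracted with TRIzol, and libraries were made from purified messenger RNA with a directional NEBNext Ultra II kit. They were sequenced on a NovaSeq instrument as paired reads of 100 bases. The values used are whole-number read counts per gene and library, as deposited by the authors. Per the submitters' processing notes, FastQC, TopHat, Cufflinks and edgeR were used with the human assembly hg19 (GRCh37). The counting tool and the gene annotation are not given in the sources used here, nor is it stated whether counting used the strand of the reads. Values of overlapping or antisense genes are therefore uncertain, as are those of close paralogs such as the HLA, MAGE, GAGE and cystatin (CST1, CST2) genes.

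The table held 24424 genes, of which 4896 had no count in any library. Every row named a gene and every column of per-sample values was used. Library totals were 19430130 (shEmpty), 14181829 (shBAP1) and 18456328 (shPRAME). A gene without a count was given a floor of 3 counts, or 0.160, 0.202 and 0.164 CPM in that order, and its fold is a lower bound at that floor, while the ranking of such genes used the lower bound of the wider 2-sided interval. No library was left out. Pearson correlations across the measured genes, on log2 of CPM plus 1, were 0.885 (shPRAME with shEmpty), 0.910 (shBAP1 with shEmpty) and 0.819 (shPRAME with shBAP1).

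Counts were scaled with TMM factors (edgeR 4.0.16, R 4.3.3) over the 3 libraries, and log2 ratios were taken without a pseudocount. Genes with a mean count of at least 50 were measured (11956). The size rule required an absolute log2 ratio of at least 1 and an exact 95% interval, from the conditional binomial distribution, that left out no change. 3 comparisons were made: shPRAME with shEmpty, shBAP1 with shEmpty, and shPRAME with shBAP1. The comparisons, gene lists, rules and most alternatives were fixed before the data were examined.

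For 34 gene lists the median log2 ratio of measured members was placed among those of 10000 random lists of the same size, matched in 20 bins of mean expression. A list with at least 5 measured members stood apart when its percentile was among the lowest or highest 2.5%. The list of mitochondrially encoded genes had none of its genes in the table and was not analysed here. Gene families and 2 lists of senescence-related genes were chosen after the data were seen and appear only in the closing section. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

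Named genes followed a rule. PRAME and BAP1 were always named. For each comparison with shEmpty the 10 highest and 10 lowest genes past the size rule were named, ranked by the interval bound nearest no change, and 5 each in the direct comparison. For the overlap, 5 genes were named per shared direction and up to 3 per opposite direction. For each list up to 4 members with the largest absolute ratio were named where it stood apart and up to 2 otherwise. Genes outside the rule are described as chosen after their values were seen. Some genes that the rule names are not reported here.

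The overlap of the knockdowns was set beside 100 simulated draws of unchanged libraries, with Poisson counts or negative binomial counts at assumed biological coefficients of variation of 0.1, 0.2 and 0.4. Chromosomes, GC content and transcript length came from GENCODE release 29 (GRCh38), matched by gene symbol for 11400 of the measured genes (95.3%). That annotation is newer than the assembly of the files, so it served only to group genes. A chromosome was shifted where its median lay over 0.3 log2 from that of all genes, and GC and length trends were removed by local regression with a span of 0.3.

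The procedure was tested on simulated data for each comparison, with counting error only. All genes made 3-, 4- or 8-fold different were called in each of the 3 comparisons. Genes made 1.5-fold different were called in 0% of cases with shPRAME or shBAP1 against shEmpty and 2.04% in the direct comparison. Of the unchanged genes 0%, 0% and 0.0085% were called. Random lists stood apart in 3.5%, 5.5% and 5.5% of draws, and lists shifted by 0.5 log2 in 100%. Alternatives were total-count, upper-quartile and DESeq2 (1.42.0) scaling, count minima of 10, 200 and none, fold limits of 1.5 and 3, a whole interval beyond 2-fold and a pseudocount of 1 CPM. For lists they also included the mean, 10 expression bins and random lists without matching. Subtraction of chromosome medians and removal of GC and length trends were added after the data were seen.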

Results

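Messenger RNA was sequenced from A375SM, a metastatic line derived from the human melanoma line A375, after lentiviral delivery of short hairpin RNAs. 3 stable populations were compared, with a hairpin against PRAME (shPRAME), a hairpin against BAP1 (shBAP1) or a control vector (shEmpty). The labels differ on whether the control carried a non-targeting hairpin, so an effect of any hairpin may be part of what both knockdowns share. PRAME is a cancer-testis antigen of many melanomas whose product binds the CUL2 ubiquitin ligase and is known as a repressor of retinoic acid receptor signalling. BAP1 is a nuclear deubiquitinase that removes ubiquitin from histone H2A, and it is a tumour suppressor in uveal melanoma and mesothelioma. The comparisons address which transcripts differ from the control in the library where either protein's messenger is lowered. Each target was lowered in 1 population, so effects of a hairpin on other genes cannot be told apart from those of lowering its target.

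Each group was 1 library, so no difference has a replicate check and no p-value was computed. The count table listed 24424 genes. The libraries held 19430130 counts over 17386 genes (shEmpty), 14181829 counts over 17505 genes (shBAP1) and 18456328 counts over 17980 genes (shPRAME). A count of 0 allows up to 3 counts, which is 0.160 CPM (counts scaled to library size) in shEmpty, 0.202 in shBAP1 and 0.164 in shPRAME. 11956 genes had a mean count of at least 50 and were measured. A gene is called higher or lower where its scaled count differed by at least 2-fold and the exact 95% counting interval of the ratio left out no change. Such calls compare these libraries, not the conditions, and the intervals and floors cover counting error only. Folds are scaled-count ratios, given with that interval where it is wide or a count was 1 to 3, and as a lower bound where a count was 0.

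PRAME and BAP1 were each lowest in the library with the matching hairpin. PRAME (chromosome 22) was at 327 CPM in shEmpty (319 to 336), 108 CPM in shPRAME (103 to 112) and 455 CPM in shBAP1 (444 to 466). It therefore stood at 32.9% of the control in shPRAME (31.2% to 34.6%) and was 1.39-fold higher in shBAP1 (1.34 to 1.44). BAP1 (chromosome 3) was at 100.0 CPM in shEmpty (95.5 to 105), 35.2 CPM in shBAP1 (32.2 to 38.3) and 97.9 CPM in shPRAME (93.4 to 103). It stood at 35.2% of the control in shBAP1 (31.8% to 38.8%) and at 97.9% in shPRAME (91.7% to 104%), a ratio whose sign changed with the scaling.

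**Figure D1:**
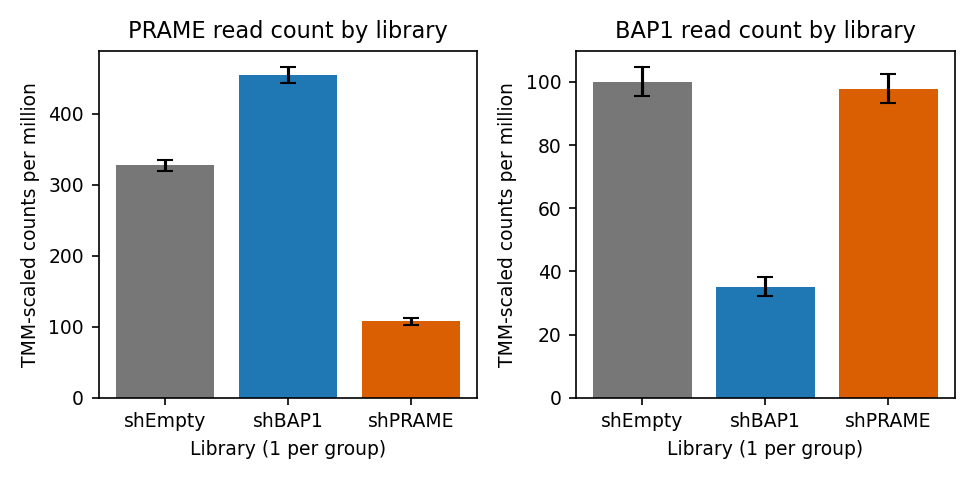
Scaled read count (CPM, y axis) of PRAME and of BAP1 in each library (x axis, 1 library per group). Bars are the value and lines its exact 95% Poisson interval, which covers counting error only. PRAME was lowest in shPRAME at 108 CPM and BAP1 was lowest in shBAP1 at 35.2 CPM.

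In the shPRAME library, genes of DNA replication, mitosis and DNA repair and the MHC class II genes were lower than in shEmpty. Genes of the extracellular matrix, some inflammatory cytokine genes and immediate early transcription factors were higher. Of the 28 measured G2/M and mitosis genes, 27 were lower, with a median log2 ratio of -1.53. CXCL8, the neutrophil chemoattractant interleukin 8, was 42.6-fold higher (39.9 to 45.4), and CD74, the invariant chain of MHC class II, was 249-fold lower (156 to 429). In all, 2311 of the 11956 measured genes passed the size rule, 1225 higher and 1086 lower.

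Genes were ranked by the near bound of their interval, and the 10 highest in shPRAME began with NTS. NTS, the precursor of the peptide neurotensin, was 837-fold higher (384 to 2283), on 6 counts in shEmpty. CHRDL1, a secreted antagonist of bone morphogenetic proteins, was 1199.5-fold higher (332 to 9911), on 2 counts in shEmpty, and RELN (reelin) was 403-fold higher (185 to 1098). PRSS3, a trypsinogen, and DOK5, an adaptor of receptor tyrosine kinases, had no count in shEmpty and were at least 220.0-fold and at least 185-fold higher. STMN2, a neuronal microtubule regulator, was 769.6-fold higher (138 to 30439) on 1 count in shEmpty. DIO2, which activates thyroid hormone, was 164-fold higher (89.0 to 343). The collagen chain COL1A2 was 105-fold higher (88.1 to 127), the collagen receptor ITGA11 99.0-fold (62.4 to 167) and COL22A1 71.9-fold (61.7 to 84.3). At the other end stood CD74, the MHC class II chain HLA-DRA (426-fold lower, 146 to 2070.4) and the growth factor receptor FGFR2 (425-fold lower, 76.0 to 16842). The salivary cystatin CST2, the homeobox gene EMX2 and the prohormone convertase PCSK2 had no count in shPRAME and were at least 184-fold, at least 74.5-fold and at least 57.2-fold lower. NELL1 was 177-fold lower (68.9 to 652), the cancer-testis gene PAGE5 106-fold (58.9 to 213), PROM1, which encodes the stem cell marker CD133, 114-fold (57.5 to 264) and the pentraxin NPTX1 75.6-fold (44.8 to 139).

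Of 34 gene lists, 30 had at least 5 measured members. In shPRAME 9 of these stood apart above and 8 below random lists of the same size and expression. With 30 lists of genes drawn at random 1.5 would do so. The lists used here share genes, 9 of the invasive-state list belonging to others too, so their calls are not independent. These percentiles describe the libraries and are not a test of the conditions.

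Proliferation genes made up the most uniform group in shPRAME. Of 26 measured G1/S and DNA replication genes 24 were lower and 2 passed in neither direction, and the median log2 ratio of -1.54 lay below those of all 10000 random lists. RRM2, the small subunit of ribonucleotide reductase, was 11.7-fold lower, CDC25A 6.91-fold and the replication licensing factor CDC6 5.58-fold. Among the G2/M genes, whose median also lay below all random lists, KIF23 was 4.80-fold lower, the mitotic transcription factor FOXM1 4.50-fold, AURKA 4.32-fold and cyclin A2 (CCNA2) 4.04-fold. Of 24 homologous recombination and DNA damage repair genes 14 were lower and 1 higher, with a median of -1.10. EXO1 was 5.06-fold lower, BRCA2 3.98-fold and RBBP8 3.68-fold. Only 4 of 15 replication-dependent histone genes were measured, too few for a percentile; HIST1H2BJ was 3.21-fold lower and HIST2H2BE had a ratio of 1.88-fold upward, within the 2-fold limit.

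Matrix and mesenchymal genes were higher in shPRAME. Of 27 measured genes of the epithelial-mesenchymal and extracellular matrix list, 11 were higher, none lower and 16 neither, with a median of 0.77, above all random lists. Besides COL1A2, COL5A1 was 25.6-fold higher (8.44 to 127, on 3 counts in shEmpty), fibronectin (FN1) 7.76-fold and the gelatinase MMP2 6.69-fold. The list of the dedifferentiated and invasive melanoma state had 9 of 21 genes higher and 1 lower, with a median of 0.77. COL13A1 was 14.9-fold higher, the receptor tyrosine kinase AXL 7.99-fold and PLAUR 5.42-fold. Of 16 TGF-beta and SMAD targets 6 were higher and 1 lower (median 0.56, percentile 99.93), among them the activin subunit INHBA (18.3-fold higher), LTBP2 (7.56-fold) and TGFB1 (4.01-fold). The fibroblast marker list, of which 7 of 14 genes were measured and 5 belong to other lists too, had a median of 1.04 (percentile 99.64) with 4 genes higher. These were COL1A2, PDGFRB (4.98-fold), FAP (2.28-fold) and FBLN1 (2.06-fold). Other transcripts abundant in fibroblasts, chosen after their values were seen, were scarce in shPRAME, where COL1A1 had 23 counts, COL3A1 13 and DCN 49, beside 12250 for COL1A2.

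Some cytokine genes and signal-responsive genes were also higher in shPRAME. The list of NF-kB and inflammatory cytokine genes had 14 of 27 genes measured, with 5 higher and none lower (median 0.80, percentile 99.97). Members below the count minimum, chosen after their values were seen, included IL6 (0 counts in shEmpty and 1 in shPRAME), CXCL1 (28 and 17) and CCL2 (0 and 0). IL1A (12 and 90) and IL1B (6 and 58), also below it, had more counts in shPRAME. LIF was 9.85-fold higher, IRAK2 4.17-fold and TRAF1 3.04-fold, next to CXCL8. Of 16 immediate early genes 8 were higher and none lower (median 1.05), with EGR2 at 4.05-fold, JUNB at 3.13-fold, EGR1 at 2.70-fold and IER2 at 2.62-fold higher. Among members below the count minimum, chosen after their values were seen, ATF3 had 58 counts in shEmpty and 10 in shPRAME, and KLF2 44 and 81. Genes that report MAPK pathway activity went both ways, 7 of 21 higher and 2 lower (median 0.28, percentile 99.3). SPRY1 was 4.21-fold higher, DUSP5 3.59-fold, DUSP6 3.56-fold and ETV1 3.23-fold, while LZTS1 (3.19-fold) and DUSP4 (2.02-fold), both chosen after their values were seen, were lower. The MAPK call ended with the count minimum at 10 (median 0.20).

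MHC class II genes were the lowest list in shPRAME, with 8 of 10 lower, 1 higher and a median of -2.59, below all random lists. With CD74 and HLA-DRA, CIITA, the transactivator of the class II genes, was 84.4-fold lower (32.7 to 312) and HLA-DRB1, with no count in shPRAME, at least 46.8-fold lower. HLA-DQB1, chosen after its value was seen, was 3.70-fold higher. Of 16 MHC class I presentation genes none passed in either direction (median 0.20, percentile 92.4), with NLRC5 at 1.98-fold higher and TAP2 at 1.75-fold lower. The 18 interferon-stimulated genes were split, 3 higher and 3 lower (median 0.26, percentile 86.5), with IRF7 2.57-fold higher and OAS3 3.4-fold lower.

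Several pigment-cell genes were lower in shPRAME. Of 17 measured genes of melanocyte differentiation and pigment, 7 were lower, none higher and 10 neither, with a median of -0.76 (percentile 0.04). TYR (4 counts in shEmpty and 0 in shPRAME) and TYRP1 (0 and 1) were measured only through shBAP1 (573 and 1037). The floor of 3 counts gave TYRP1 a downward ratio although its count was not lower in shPRAME. PMEL (6 and 8) and MLANA (3 and 7) were below the count minimum. These 4 genes were chosen after their values were seen. DCT, an enzyme of melanin synthesis, was 31.2-fold lower (14.1 to 86.1), the melanosome trafficking gene RAB38 13.1-fold, MREG 3.72-fold and CAPN3 3.26-fold. The neural crest and neuronal list had 3 of 14 genes higher and 2 lower and did not stand apart (median 0.17), although STMN2 and GAP43 (15.5-fold) were among the higher genes.

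Lists tied to the known functions of PRAME gave the following. Of 16 retinoic acid response genes 4 were higher and none lower, with a median of 0.62 (percentile 99.97). STRA6, the cellular receptor for retinol-binding protein, was 6.29-fold higher, PDK4 3.31-fold and the receptor gene RARA 2.14-fold. None of 14 CUL2 ligase partner genes passed (median -0.17, percentile 41.2), with KLHDC10 at 1.72-fold higher and TCEB1 (elongin C) at 1.65-fold lower. Of 12 cancer-testis antigen genes 3 were higher and 1 lower, with a median of -0.22 (percentile 22.8) and a mean of 0.41. MAGEA10 was 122-fold higher (21.5 to 4857, on 1 count in shEmpty), against PAGE5 on the lower side.

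The medians of oxidative phosphorylation and ribosomal protein genes stood apart as lower in shPRAME with 1 gene of each past the rule. Of 27 nuclear oxidative phosphorylation genes 1 was lower and 26 neither (median -0.57, percentile 0.08). That gene was PPARGC1A, a coactivator of mitochondrial biogenesis, 14.1-fold lower (7.85 to 27.8), followed by UQCRQ (1.94-fold), COX5B (1.88-fold) and ATP5O (1.83-fold). Of 28 cytosolic ribosomal protein genes 1 was lower and 27 neither (median -0.62, percentile 1.51), with RPS3 at 2.02-fold, RPL10A at 1.99-fold, RPS23 at 1.93-fold and RPS27A at 1.88-fold lower. Both calls ended once trends with GC content and transcript length were removed, a step chosen after seeing the data (medians -0.37 and -0.53). Of 20 ferroptosis and glutathione genes 7 were lower and 1 higher (median -0.51, percentile 1.89). CHAC1 was 7.53-fold lower, the cystine transporter SLC7A11 6.18-fold, TXNRD1 3.89-fold and HMOX1 3.02-fold, and the call ended without a count minimum (median -0.47). The unfolded protein response and ATF4 list had 9 of 24 genes lower and 2 higher without standing apart (median -0.23, percentile 25.5), and the serine synthesis gene PSAT1 was 9.34-fold lower.

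The remaining lists were as follows. Of 24 p53 targets 5 were higher and 1 lower (median 0.34, percentile 99.44), with BTG2 5.07-fold, TP53INP1 3.91-fold and PLK3 2.76-fold higher and CCNG1 2.38-fold lower. This call ended with the mean in place of the median and once GC and length trends were removed (median 0.08). HOX and other Polycomb-target regulators had 4 of 29 genes higher and 1 lower (median 0.31, percentile 95.1), with HOXA5 3.98-fold higher and HOXD13 3.64-fold lower. BAP1 complex partners and Polycomb subunits had 2 of 34 higher and 5 lower (median -0.22, percentile 16.3), with MBD5 3.17-fold higher and PHF19 3.12-fold lower. Of 22 apoptosis regulators 2 were higher and 3 lower (median -0.23, percentile 16.2), among them the antiapoptotic gene BCL2 at 27.9-fold lower (15.0 to 58.8). Of 23 hypoxia and glycolysis genes 1 was higher and 3 lower (median -0.35, percentile 15.4), with P4HA2 3.89-fold higher and LDHA 2.5-fold lower. The cholesterol synthesis list had 1 of 22 genes higher, STARD4 (2.14-fold), and a median of 0.00 (percentile 77.8). The 7 Wnt and beta-catenin targets had a median of -0.08 (percentile 47.3), which changed sign under upper-quartile scaling, and a mean of 0.27, with TCF7 4.99-fold higher and NKD1 4.22-fold lower. Of other cell types' markers, the 5 measured endothelial genes had a median of 0.19 (percentile 74.3), with TIE1 123-fold higher (41.6 to 597, on 3 counts in shEmpty) and FLT1 7.71-fold lower. 1 keratinocyte gene (KRT10, a ratio of 1.25-fold downward) and 1 immune cell gene (CD68, 2.94-fold higher) were measured, too few for a percentile.

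**Figure D2:**
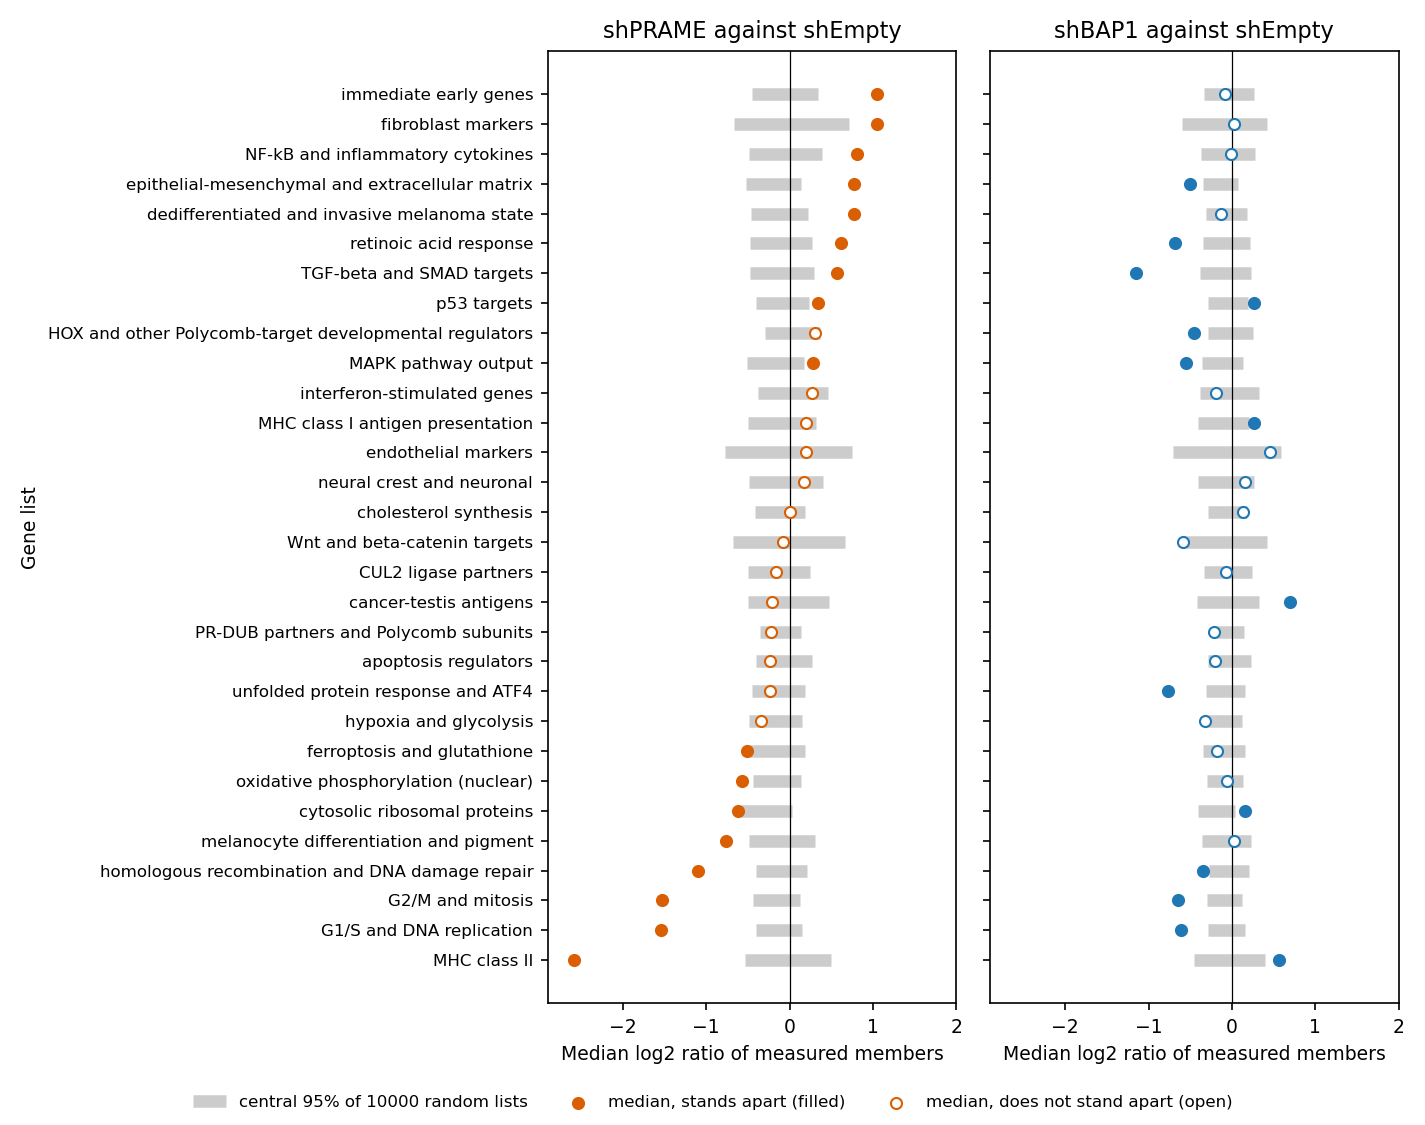
Median log2 ratio (x axis) of the measured members of each gene list (y axis) in shPRAME and in shBAP1, each against shEmpty. Grey bars hold the central 95% of 10000 random lists of the same size and expression, filled points lie outside them and open points inside. MHC class II had the lowest median in shPRAME at -2.59 and the TGF-beta list the lowest in shBAP1 at -1.15.

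In the shBAP1 library, TGF-beta target genes, genes of the unfolded protein response and ATF4 and retinoic acid response genes were lower than in shEmpty, and individual pigment genes and cancer-testis genes were higher. TYRP1, an enzyme of melanin synthesis with no count in shEmpty, was at least 436-fold higher, and TYR, the rate-limiting enzyme of that pathway, was 181-fold higher (70.2 to 666). COL6A3, a collagen VI chain, was 121-fold lower (95.6 to 156), and INHBA was 32.2-fold lower (24.0 to 44.1). In all, 1685 of 11956 measured genes passed the size rule, 661 higher and 1024 lower, so that 39.2% of the calls were higher. With scaling by total count 49.8% of the calls were higher, because that scaling moved the median log2 ratio of all genes by 0.12.

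Among the 10 genes ranked highest in shBAP1, TYRP1, FSTL5 (at least 233-fold higher), the RNA-binding oncofetal gene LIN28B (at least 188-fold) and FBXL7 (at least 138-fold) had no count in shEmpty. SOHLH2, a germ-cell transcription factor, was 987-fold higher (177 to 39033) on 1 count in shEmpty and TRIM48 was 233-fold higher (122 to 509). NLRP1, an inflammasome sensor, was 219-fold higher (85.3 to 807), LINC01287 217-fold (84.3 to 798), KYNU, an enzyme of tryptophan breakdown, 161-fold (81.6 to 374.8) and FAM133A 204-fold (79.4 to 752). Of the 10 ranked lowest, VAT1L was 85.6-fold lower (61.7 to 122), FGL2 92.8-fold (42.4 to 254), NELL1 95.9-fold (43.8 to 262), COL15A1 46.3-fold (38.4 to 56.3) and CST2 89.8-fold (38.3 to 278). FGFR2 was 345-fold lower (61.7 to 13675), PRDM8 342-fold (61.1 to 13550.1) and the sodium-calcium exchanger SLC8A1 191-fold (33.9 to 7573), each on 1 count in shBAP1, and CST1, at 0 there, was at least 47.8-fold lower.

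In shBAP1 5 of 30 lists stood apart above and 9 below their random lists. The TGF-beta and SMAD targets were the lowest, with 11 of 16 lower, 1 higher and a median of -1.15, below all random lists. INHBA was joined by the SMAD inhibitor gene PMEPA1 (9.97-fold lower) and the helix-loop-helix regulator ID3 (4.25-fold lower), while CTGF was 6.08-fold higher. Of 24 unfolded protein response and ATF4 genes 7 were lower and none higher (median -0.77, below all random lists). CHAC1 was 9.74-fold lower, VLDLR 5.26-fold, asparagine synthetase (ASNS) 3.68-fold and PHGDH, the first enzyme of serine synthesis, 2.64-fold. Of 16 retinoic acid response genes 6 were lower and none higher (median -0.69, percentile 0.02), with STRA6 26.4-fold, PDK4 4.11-fold, ALDH1A3 2.57-fold and SMAD3 2.33-fold lower.

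Proliferation lists were lower in shBAP1 too, by smaller amounts. Of 26 G1/S genes 7 were lower and none higher (median -0.61), and of 28 G2/M genes 4 were lower and none higher (median -0.64), both medians below all random lists. Thymidylate synthase (TYMS) was 3.18-fold lower, CCNE2 2.64-fold and MCM4 2.35-fold, and in mitosis CDK1 was 2.80-fold lower, UBE2C 2.70-fold, CDC25C 2.25-fold and NUSAP1 2.12-fold. TYMS lies on chromosome 18 and CCNE2 and MCM4 on chromosome 8, whose genes had lower medians in this library as a whole. Of 24 DNA repair genes 1 was lower, RBBP8 (2.63-fold), and 1 higher, RAD50 (3.89-fold), with a median of -0.35 (percentile 0.69), a call that ended with the mean (-0.27). BRCA1 had a ratio of 1.85-fold and CHEK1 of 1.61-fold downward. Of the 4 measured histone genes HIST1H2BK was 7.08-fold higher and HIST1H2BJ 5.29-fold lower.

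Matrix and signalling genes went both ways in shBAP1. The epithelial-mesenchymal and extracellular matrix list had 10 of 27 genes lower and 6 higher (median -0.50, percentile 0.16). Against COL6A3 on the lower side, COL5A1 was 78.3-fold higher (26.4 to 383, on 3 counts in shEmpty), COL1A2 26.8-fold and the interstitial collagenase MMP1 5.61-fold. The call ended with the mean (-0.12) and without a count minimum (median -0.19). MAPK output genes had 4 of 21 lower and 2 higher (median -0.55, percentile 0.04), with EGR1 6.34-fold and cyclin D1 (CCND1) 4.17-fold lower and SPRY1 3.85-fold and EPHA2 3.19-fold higher. Developmental regulators of the HOX and Polycomb-target list had 6 of 29 lower and none higher (median -0.45, percentile 0.06), with TBX3 3.94-fold, GATA4 2.86-fold and HOXD9 2.68-fold lower. The MAPK and developmental regulator calls ended with the mean (-0.47 and -0.35), and the latter also without a count minimum (median -0.17). No gene among 34 BAP1 complex partners and Polycomb subunits passed (median -0.21, percentile 4.55), with RING1 at 1.92-fold higher and CBX7 at 1.80-fold lower. RING1 lies on chromosome 6, whose measured genes had a median 0.43 above that of all genes in this library.

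The cancer-testis antigen list stood apart as higher in shBAP1, with 5 of 12 genes higher, none lower and a median of 0.70 (percentile 99.99). MAGEB2 was 132-fold higher (36.1 to 1096, on 2 counts in shEmpty), MAGEA10 51.7-fold (8.78 to 2093, on 1 count), MAGEA1 14.6-fold and MAGEC1 4.92-fold, and the call ended with the count minimum at 200 (median 0.22). MAGEB2, MAGEA10 and MAGEC1, with at most 10 counts in shEmpty, were measured only through the knockdown libraries. The MAGE genes of the list with the most counts in shEmpty had log2 ratios of 0.61 (MAGEA4), -0.30 (MAGEA3), -0.39 (MAGEA6) and 0.22 (MAGEA12). The melanocyte and pigment list had 5 of 17 genes higher and none lower, yet its median of 0.02 did not stand apart (percentile 70.3), and 12 genes passed in neither direction. The invasive-state list had 6 of 21 genes higher and 3 lower (median -0.13, percentile 27.0, mean 0.22), with the nerve growth factor receptor NGFR 134-fold higher (70.1 to 293) and EGFR 23.2-fold lower (13.9 to 41.9).

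MHC genes parted in shBAP1. The MHC class II list had a median of 0.56 (percentile 99.73) and a mean of -0.40, with 2 of 10 genes higher and 2 lower. HLA-DRA and HLA-DPA1 were 2.04-fold and 2.04-fold higher, and HLA-DQA1 and HLA-DQB1 were 31.9-fold (18.1 to 62.2) and 14.2-fold (8.73 to 24.7) lower. MHC class I presentation had a median of 0.26 (percentile 99.0), with PSMB8 2.05-fold and TAPBP 2.02-fold higher and HLA-B 3.54-fold and HLA-C 2.46-fold lower. All of these genes lie on chromosome 6, whose measured genes had a median 0.43 above that of all genes in this library. With each chromosome's median subtracted, a step chosen after seeing the data, the class II median was 0.13 (percentile 79.2) and the class I median was -0.12, so neither list stood apart as higher.

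In shBAP1 the p53 targets had a median of 0.26 (percentile 99.41) with no gene higher and SESN2 2.57-fold lower, and the call ended with the mean (0.12). PHLDA3 had a ratio of 1.99-fold downward and CDKN1A, the cell-cycle inhibitor p21, and ZMAT3 ratios of 1.87-fold and 1.62-fold upward. Ribosomal protein genes had a median of 0.16 (percentile 99.97) with none of 28 past the rule, RPS18 at 1.63-fold, RPS19 at 1.32-fold and RPS6 at 1.30-fold higher and RPL8 at 1.43-fold lower, and did not stand apart from random lists without expression matching. Lists that did not stand apart were interferon-stimulated genes (median -0.19, 4 of 18 lower, CMPK2 15.4-fold and IRF7 2.89-fold lower), hypoxia and glycolysis (-0.32, 4 of 23 lower, ENO2 3.17-fold and PFKP 2.62-fold) and ferroptosis and glutathione (-0.18, 3 of 20 lower, with CHAC1 and PTGS2 9.45-fold). Apoptosis regulators had a median of -0.20 with 1 of 22 lower, BCL2A1 (2.55-fold), and a ratio of 1.85-fold downward for PMAIP1. The neural crest and neuronal list had 4 of 14 genes higher and 5 lower (0.16), led by the adhesion molecule L1CAM (40.0-fold higher) and the synaptic vesicle gene SYT1 (5.34-fold lower). Cholesterol synthesis had a median of 0.14 with DHCR7 2.27-fold higher and FDFT1 at 1.73-fold lower. The Wnt targets had a median of -0.59 (percentile 2.72) with 2 of 7 lower, LEF1 (5.52-fold) and CCND1. Fibroblast markers had a median of 0.03 with COL1A2 higher and FBLN1 9.90-fold lower, and endothelial markers a median of 0.46 with KDR 6.88-fold lower and TIE1 4.63-fold higher (1.22 to 25.8, on 3 counts in shEmpty).

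The sign of 4 medians near 0 in shBAP1 depended on the scaling. NF-kB and inflammatory cytokine genes had a median of -0.01 (0.11 with total counts), with TRAF1 4.72-fold higher and PTGS2 among 3 lower genes. Immediate early genes had a median of -0.08 (0.04 with total counts), with 2 higher and 4 lower, led by EGR2 (15.5-fold lower) and EGR3 (9.14-fold lower). Oxidative phosphorylation genes had a median of -0.05 (0.06 with total counts) and a mean of 0.04, with PPARGC1A 2.28-fold higher and COX6C at 1.58-fold lower. CUL2 ligase partners had a median of -0.07 (0.05 with total counts), with LRRC14 2.15-fold lower and KLHDC3 at 1.57-fold higher. KRT10 had a ratio of 1.58-fold and CD68 of 1.26-fold upward, as the 1 measured keratinocyte and 1 measured immune cell gene.

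Both knockdown libraries were then set against each other's differences from shEmpty. 280 genes were higher in both and 186 lower in both, 233 were higher in shPRAME and lower in shBAP1, and 55 the reverse. NLRP1 (129-fold higher in shPRAME, 50.1 to 476), LINC01287 (120.2-fold, 46.6 to 443), FAM133A (109-fold, 42.1 to 401), the muscle gene MYOZ2 and the scramblase PLSCR4 led the genes higher in both. MYOZ2 had 3 counts in shEmpty and was 112-fold higher in shPRAME (38 to 546) and 98.0-fold higher in shBAP1 (33.1 to 479). PLSCR4 had 1 count in shEmpty and was 148-fold (26.1 to 5869) and 165-fold (29.2 to 6579.8) higher. FGFR2, NELL1, CST2, NPTX1 (53.7-fold lower in shBAP1, 32.9 to 94.3) and CST1 (58.9-fold lower in shPRAME, 19.8 to 288) led those lower in both. COL22A1 and INHBA were among those ranked first of the genes higher in shPRAME and lower in shBAP1. COL22A1 was 65.8-fold lower in shBAP1 (17.9 to 548, on 2 counts), and INHBA was 18.3-fold higher in shPRAME and 32.2-fold lower in shBAP1. In the reverse direction, DCT was 31.2-fold lower in shPRAME and 11-fold higher in shBAP1. LINC00520 was 31.7-fold lower (8.43 to 267, on 2 counts) and 9.36-fold higher, and the pseudogene FRG2DP 10.1-fold lower and 12.4-fold higher.

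These overlaps share 1 control library, which adds common chance values. Lists of these sizes drawn independently would share 67.7 higher, 93.0 lower, 105 higher-lower and 60 lower-higher genes. Across the 11956 genes, which are not independent replicates, the log2 ratios correlated with a Pearson r of 0.185 and a Spearman rho of 0.132. With a count minimum of 200 r was 0.0890 and 222 genes passed in both in the same direction, and without a minimum r was 0.322 and 882 genes did. Simulated unchanged libraries against the shared control gave a mean r of 0.467 with counting error alone and up to 0.499 with an assumed biological coefficient of variation of 0.4, all above the observed r. Differences particular to 1 knockdown library would lower r, and the simulated libraries held none. The lower observed r therefore does not decide whether the knockdowns share changes. The observed covariance was 0.191, against simulated means of 0.00633, 0.0274, 0.0919 and 0.370 at assumed coefficients of 0, 0.1, 0.2 and 0.4. Genes past the rule in both in the same direction numbered 466, against simulated means of 0, 0.26, 36.1 and 1013 at those coefficients. Genes past it in opposite directions numbered 288, against an independent expectation of 165 and simulated means of 0, 0, 0.02 and 37.5. The same-direction count and the covariance lay between the simulated means at 0.2 and 0.4, while the opposite-direction count lay above every simulated mean. The control could not be split, so part or all of the same-direction excess over independent lists may come from the shared control.

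**Figure D3:**
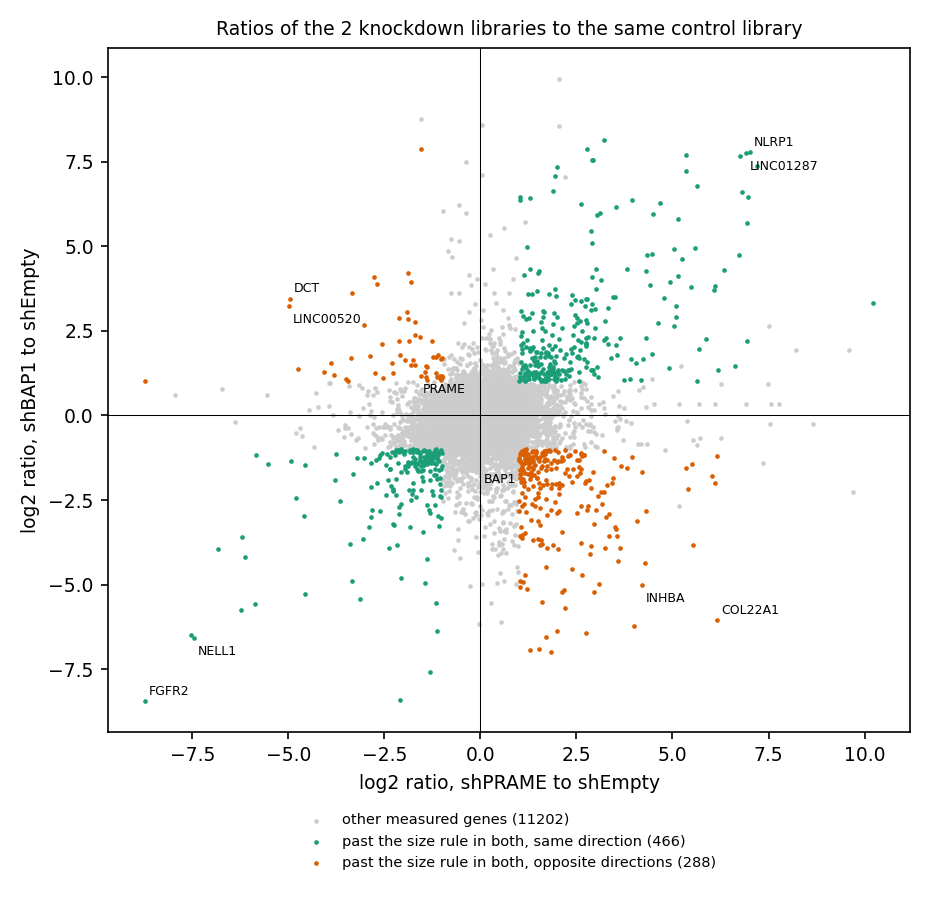
Log2 ratio to shEmpty in shPRAME (x axis) and in shBAP1 (y axis) for each measured gene, 1 point per gene. Green points passed the size rule in both libraries in the same direction (466 genes) and orange points in opposite directions (288 genes); both ratios use the same control library.

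The direct ratio of shPRAME to shBAP1 does not use the control, and 3006 genes passed the rule in it, 1702 higher and 1304 lower in shPRAME. The share of higher genes was 56.6% and with total-count scaling 50.1%. Matrix and TGF-beta family genes were higher in shPRAME and pigment and MHC class II genes were higher in shBAP1. The 5 genes ranked highest were COL22A1 (4726-fold higher in shPRAME, 1308 to 39033), NTS (3980.3-fold, 714 to 157244), INHBA (589-fold, 441 to 805), VAT1L (580.3-fold, 419 to 829) and COL6A3 (298-fold, 235 to 383). The 5 ranked lowest were TRIM48 (at least 681-fold lower), HLA-DRA (870.3-fold lower, 297 to 4224), CD74 (383-fold, 239 to 658), TYRP1 (1277-fold, 229 to 50492) and TYR (at least 235-fold lower). PRAME was 4.23-fold lower and BAP1 2.78-fold higher in shPRAME than in shBAP1.

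In the direct ratio 11 of 30 lists stood apart above and 7 below. The higher lists were TGF-beta targets (median 2.0, 11 of 16 higher, PMEPA1 13.9-fold), fibroblast markers (1.98, PDGFRA 11-fold), Wnt targets (1.43, CCND1 6.31-fold) and retinoic acid response (1.32, 9 of 16 higher, STRA6 166-fold). They also included immediate early genes (1.18, EGR1 17.1-fold), extracellular matrix (1.04, 14 of 27 higher, COL6A2 25.4-fold), the neural crest list (0.87, SYT1 15.1-fold) and developmental regulators (0.54, TBX3 8.14-fold). MAPK output (0.53, DUSP6 6.32-fold), NF-kB (0.50, percentile 97.9, CXCL8 193-fold) and the ATF4 list (0.36, VLDLR 7.46-fold) were the remaining higher lists. The lower lists were MHC class II (-3.36, 8 of 10 lower, CIITA 74.2-fold), pigment (-1.06, 9 of 17 lower, DCT 342-fold), G2/M (-0.90, 11 of 28 lower, KIF23 3.09-fold) and G1/S (-0.81, 11 of 26 lower, RRM2 7.45-fold). Ribosomal proteins (-0.75, 8 of 28 lower, RPL10A 2.33-fold), DNA repair (-0.73, 7 of 24 lower, BRCA2 3.63-fold) and oxidative phosphorylation (-0.46, 5 of 27 lower, UQCRQ 2.84-fold) were the others. The NF-kB call lay near its limit and ended under 7 alternatives, and the fibroblast and Wnt calls ended with the count minimum at 10 (medians 0.51 and 0.17). The fibroblast call also ended with a minimum of 200 and the Wnt call without one. With the mean the ATF4, developmental regulator, neural crest and Wnt calls ended (0.25, 0.58, 0.46 and 1.05).

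The lists that did not stand apart in the direct ratio were the invasive state (median 0.31, percentile 97.0, EGFR 120.5-fold higher), p53 targets (0.11, PHLDA3 4.63-fold higher), interferon-stimulated genes (0.23) and MHC class I (0.10, HLA-B 4.93-fold higher). Cancer-testis antigens had a median of -0.40, with PAGE5 182-fold lower, ferroptosis and glutathione -0.33, cholesterol synthesis -0.17, CUL2 partners -0.12 and endothelial markers 0.21. Medians and means differed in sign for hypoxia and glycolysis (-0.12 and 0.23), for BAP1 partners and Polycomb subunits (-0.14 and 0.007) and for apoptosis regulators (0.04 and -0.16). The last median changed sign with total-count scaling.

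Whole chromosomes differed between the libraries, with gene positions taken by symbol for 11400 measured genes. In shPRAME the median log2 ratio, relative to that of all genes, was 0.45 for the 578 genes of chromosome 7, -0.57 for the 204 genes of chromosome 13 and -0.62 for the 161 genes of chromosome 18. In shBAP1 it was 0.43 for the 573 genes of chromosome 6, -0.50 for the 416 genes of chromosome 8 and -0.59 for chromosome 18. In the direct ratio chromosomes 13 (-0.74), 8 (0.60) and 6 (-0.36) lay beyond 0.3, while chromosome 18 lay at -0.005. COL1A2, INHBA and RELN, among the higher genes of shPRAME, lie on chromosome 7, BRCA2 and DCT on chromosome 13 and BCL2 and RBBP8 on chromosome 18. Of the genes named with upward ratios in shBAP1, RING1, CDKN1A, RPS18 and KLHDC3 lie on chromosome 6. Of those with downward ratios there, LRRC14, COX6C, RPL8 and FDFT1 lie on chromosome 8.

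**Figure D4:**
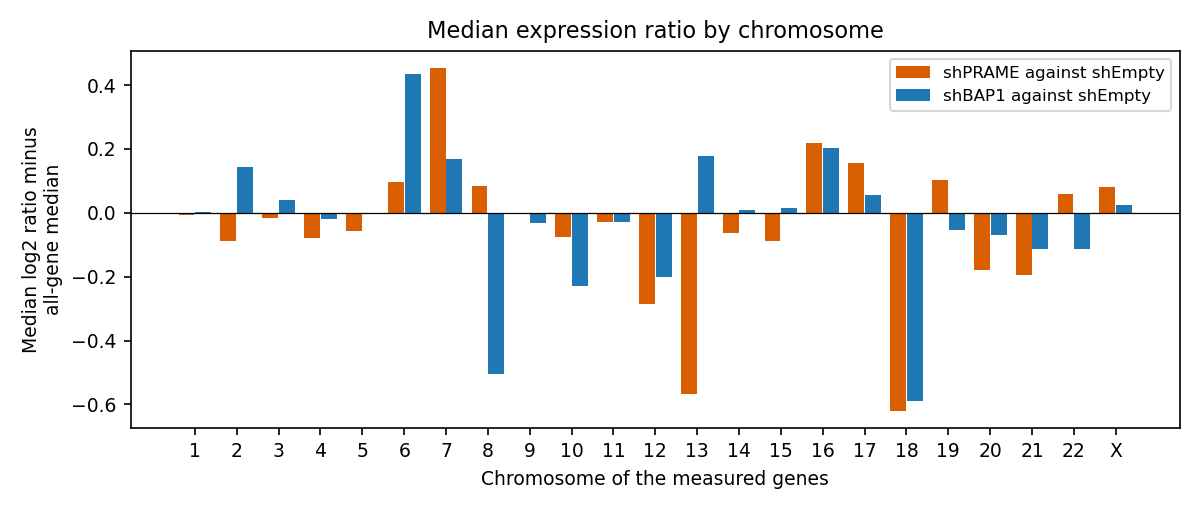
Median log2 ratio of the measured genes of each chromosome (x axis) minus the all-gene median (y axis), for shPRAME and shBAP1 against shEmpty. Chromosome 18 was lower in both libraries, at -0.62 and -0.59, and departed most in each while lying at -0.005 in their direct ratio, followed by chromosomes 13 and 7 in shPRAME and chromosomes 8 and 6 in shBAP1.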

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

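Planned and later tests are mixed in this part. The shared-control test of the proliferation lists was chosen after the result was seen. The chromosome and GC and length alternatives were also added after the data were seen.

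Whole chromosomes were shifted in each comparison, and the 6 shifts in the comparisons with shEmpty were tested. After GC and length trends were removed, the smallest distance of these chromosomes' medians from the all-gene median was 0.427 log2. GC and length trends therefore do not account for these 6 shifts. Before that removal at least 73.9% of the genes of each lay on the shifted side. The chromosomes were chosen by their medians, which already places most of their genes on that side. The share therefore gives no separate test of a few strongly differing neighbours. Each chromosome's genes were also split at the middle of their order. In shPRAME the first and second parts lay at 0.42 and 0.47 (chromosome 7), -0.66 and -0.50 (13) and -0.66 and -0.60 (18). In shBAP1 they lay at 0.41 and 0.46 (6), -0.52 and -0.50 (8) and -0.70 and -0.52 (18). A few neighbouring genes would not move the medians of both parts, so these values argue against that explanation for the 6 shifts. The chromosome 18 shifts share the control, and its direct ratio lay at -0.005, so a higher value in shEmpty could give both. A copy number difference between the cell populations was not tested, since no DNA was measured, nor was an effect of the hairpins on whole chromosomes.

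Of the lists, 6 stood apart in opposite directions in the knockdowns. Their direct medians, shPRAME to shBAP1, were 1.32 for retinoic acid response, -3.36 for MHC class II, 1.04 for extracellular matrix, 0.53 for MAPK output, -0.753 for ribosomal proteins and 2 for TGF-beta targets. The direct ratio is the difference of the ratios to shEmpty and so gives no separate test of them, and other settings ended the call in shBAP1 of MHC class II (mean -0.403), extracellular matrix (mean -0.120), MAPK output (mean -0.472) and ribosomal proteins (random lists without matching) and in shPRAME of MAPK output (0.20 with a count minimum of 10 or none, and without matching). With chromosome medians subtracted 5 of 6 kept opposite calls, MHC class II in shBAP1 being the exception (median 0.56 before and 0.13 after), and with GC and length trends removed also 5 of 6, where ribosomal proteins in shPRAME ended (-0.62 before and -0.53 after) and MAPK output there was barely kept (0.28 before and 0.07 after, percentile 97.7). Chance in either knockdown library and different clonal composition of the selected populations were not tested.

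The G1/S, G2/M and DNA repair lists were lower in both knockdowns, although in shBAP1 DNA repair had 1 of 24 genes lower and 1 higher and its call ended with the mean (-0.271). All 6 calls of 6 were kept with GC and length trends removed, and all 6 with chromosome medians subtracted. The part common to both, a G2/M median of -0.644 in shBAP1, cannot be told apart from a chance high value in the 1 control library. Cell density at harvest could also move these genes and was not tested.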

How the results depend on the processing

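Of 15 alternatives, 2 were chosen after the result was seen, the subtraction of chromosome medians and the removal of GC and length trends. The fold limits and the whole-interval rule apply to genes and not to list medians. Of the 49 list calls in the 3 comparisons, 29 were kept in every alternative that applies to lists. These were 12 of 17 in shPRAME, 5 of 14 in shBAP1 and 12 of 18 in the direct ratio. The cause was not tested for any of the departures that follow. No paired analysis was possible because each group was 1 library and the shared replicate number pairs nothing.

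With a 1.5-fold limit 4903 genes passed in shPRAME (2321 higher, 2582 lower), 3645 in shBAP1 (1522 higher, 2123 lower) and 5749 in the direct ratio (2844 higher, 2905 lower), and 1217 passed in both knockdowns in the same direction. With a 3-fold limit the numbers were 991 (592 higher, 399 lower), 778 (308 higher, 470 lower), 1361 (920 higher, 441 lower) and 189, against 2311, 1685, 3006 and 466 with 2-fold. With the whole interval beyond 2-fold 1098 genes passed in shBAP1, 414 of them higher, 868 were lower in the direct ratio and 258 passed in the same direction in both.

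With a count minimum of 10, 1903 genes were higher in shPRAME, 2543 passed in shBAP1 with 1169 higher, 763 passed in the same direction in both and the correlation of the ratios was 0.247. The MAPK list in shPRAME (0.20), MHC class I in shBAP1 (0.160) and in the direct ratio NF-kB (0.274), Wnt (0.168) and fibroblast markers (0.514) no longer stood apart. With a minimum of 200, 1534 genes passed in shPRAME with 700 higher, 1008 in shBAP1 with 320 higher and 222 in the same direction in both, and the correlation was 0.0890. Ferroptosis in shPRAME (-0.466), cancer-testis antigens in shBAP1 (0.217) and NF-kB (0.274) and fibroblast markers (0.514) in the direct ratio ended, and MHC class I in shBAP1 turned to -0.106. Without a minimum 3774 genes passed in shPRAME with 2301 higher, 3016 in shBAP1 with 1530 higher, 4727 in the direct ratio (2670 higher, 2057 lower) and 882 in the same direction in both, with a correlation of 0.322. MAPK (0.20) and ferroptosis (-0.466) in shPRAME, MHC class I (0.160), extracellular matrix (-0.193) and HOX (-0.169) in shBAP1, and NF-kB (0.264), neural crest (0.362) and Wnt (0.168) in the direct ratio ended.

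With the mean in place of the median, p53 targets ended in shPRAME (0.331) and in shBAP1 (0.124). In shBAP1 MHC class I (0.0311), extracellular matrix (-0.120), MAPK output (-0.472), DNA repair (-0.271) and HOX (-0.352) ended too, and MHC class II turned to -0.403. In the direct ratio the ATF4 list (0.248), HOX (0.577), neural crest (0.462) and Wnt (1.05) ended. With random lists not matched on expression, MAPK output in shPRAME (0.276) and MHC class I (0.259) and ribosomal proteins (0.162) in shBAP1 did not stand apart, and with 10 bins NF-kB in the direct ratio (0.499) did not.

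With GC and length trends removed p53 targets (0.0849), oxidative phosphorylation (-0.374) and ribosomal proteins (-0.534) in shPRAME and NF-kB in the direct ratio (0.103) ended. With chromosome medians subtracted MHC class I in shBAP1 turned to -0.124, and MHC class II there (0.129) and NF-kB in the direct ratio (0.440) ended.

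Scaling moved the totals little, to between 2295 and 2316 in shPRAME, 1660 and 1687 in shBAP1, and 3010 and 3083 in the direct ratio, but moved the directions more. In shPRAME 1263 to 1400 genes were higher and 916 to 1045 lower, against 1225 and 1086, and in the direct ratio 1545 to 1759 higher and 1254 to 1538 lower, against 1702 and 1304. Upper-quartile scaling put PRAME in shPRAME at 0.349 of the control, beyond the counting interval given in the report, and NF-kB in the direct ratio at 0.514, no longer apart. BAP1 in shPRAME, just below the control in the report, was just above it with total-count and upper-quartile scaling (log2 0.01 and 0.06). The share of higher genes in shBAP1 was 39.2% and with total counts 49.8%.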

Other observations

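The gene families and the 2 senescence-related lists in this part were chosen after the result was seen, so their medians only describe these libraries. Collagen genes, grouped by symbol, had 13 of 24 higher and 1 lower in shPRAME with a median log2 ratio of 1.44, led by COL1A2 (6.72) and COL22A1 (6.17). In shBAP1 10 were higher and 8 lower, with COL8A1 at 6.04, COL14A1 at 3.07 and COL6A3 at -6.92. COL6A1 and COL6A2, which assemble with COL6A3 into collagen VI, were at 2.57 and 2.74 in shPRAME and at -1.32 and -1.93 in shBAP1. Integrins had 7 of 17 higher and 2 lower in shPRAME (median 0.81), with the collagen receptors ITGA11 at 6.63 and ITGA1 at 3.50, while ITGA10 was at 1.17 in shPRAME and -2.84 in shBAP1.

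Semaphorins, guidance molecules of axons and vessels, had 7 of 17 higher and 1 lower in shPRAME (median 0.88), with SEMA6B at 3.49 in both knockdowns and SEMA3A at 2.63 and SEMA7A at 2.62 in shPRAME. RGS proteins, which shorten G-protein signalling, had 6 of 11 higher and none lower in shPRAME (median 1.23), with RGS5 at 6.10 and RGS4 at 4.30, while RGS4 was at -2.83 and RGS16 at 3.29 in shBAP1. Beta-tubulin genes had 5 of 7 lower and none higher in shPRAME (median -1.17), among them TUBB6 at -2.84 and TUBB4B at -1.70, and 2 lower and 1 higher in shBAP1 (median -0.87), with TUBB6 at -1.41 and TUBB4A at 4.08. Frizzled receptors had 5 of 9 lower and none higher in shBAP1 (median -1.01), with FZD9 at -2.27, FZD1 at -2.24 and FZD4 at -1.91, and FZD4 was at -2.40 in shPRAME. Of 6 genes grouped by the symbol FGF, 4 were lower in shBAP1 (median -1.85). The lower genes were FGF14 at -2.21, FGF12 at -2.18, FGF13 at -1.82 and the binding protein gene FGFBP2 at -1.88. FGF1 was at 2.12 and FGF2 at 0.27, so the median does not describe all fibroblast growth factors. MAGE genes had 7 of 14 higher and none lower in shBAP1 (median 0.95) and 5 higher in shPRAME (median 0.70).

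Some genes passed from nearly no counts to many. In all, 123 genes had at least 100 counts in 1 library and at most 3 in another. With a wider limit of 4 counts, FAM133A, LIMCH1, LINC01287, MYOZ2, NCALD, NLRP1 and PLSCR4 were scarce in shEmpty and had 100 or more counts in both knockdown libraries. Of these, FAM133A, LIMCH1, LINC01287 and NLRP1 had 4 counts in shEmpty and so exceeded the limit of 3. LIMCH1 had 347 counts in shBAP1 and 196 in shPRAME. NCALD had 2 counts in shEmpty, 138 in shBAP1 and 242 in shPRAME. In the reverse direction, BMP7, CST1, FGFR2 and WFDC1 had at least 100 counts in shEmpty and at most 3 in both knockdown libraries. Both sets use the same control library, and whether their counts are particular to it was not tested.

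Within MHC class II the HLA-DQ genes ran against the other members. HLA-DQA1 had 483 counts in shEmpty, 894 in shPRAME and 12 in shBAP1, and HLA-DQB1 had 305, 1101 and 17. CIITA had 346 counts in shEmpty, 241 in shBAP1 and 4 in shPRAME, so the HLA-DQ counts were highest in the library with the least CIITA.

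The 2 senescence-related lists were written after the lower proliferation genes and higher secreted factors of shPRAME were seen and share genes with the families above, so they do not test for senescence. Of 36 secreted factors described in senescent cells 20 were measured, with 8 higher and none lower in shPRAME (median 0.74). Among them were IL11 at 4.29, IGFBP6 at 2.63, IGFBP3 at 2.51 and IGFBP4 at 2.19, against CXCL16 at -0.99, IGFBP7 at -0.42 and MMP3 at -0.36. Other such factors were scarce in shPRAME, where IL6 had 1 count, CXCL1 17 and CXCL2 and CCL2 0. IL1A (12 counts in shEmpty and 90 in shPRAME) and IL1B (6 and 58) had more counts in shPRAME, and CXCL8, outside this list, was also higher there. In shBAP1 the list had 4 higher and 8 lower genes (median -0.39). Genes described as lower in senescent cells had 12 of 15 lower in shPRAME (median -1.30), among them LMNB1 at -2.25 and H2AFZ at -2.80, and none past the rule in shBAP1 (median -0.53).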
